A study of Homo sapiens with 6 samples.

How the data were processed

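RNA was sequenced from 6 cryopreserved tumours of 3 patients with oral squamous cell carcinoma, 1 primary and 1 recurrent tumour each. Per the labels' protocols, the tissue was moved to RNAlater-ICE, RNA was extracted with a column kit and libraries were made with a stranded kit that selects polyadenylated mRNA. The submitters' processing notes name FastQC, STAR, edgeR and the genome build GRCh38.p13; the counting program, its strand setting and the annotation release are not given in the sources used here. The deposited count table holds whole read counts for 60668 genes of all biotypes in the 6 libraries, with RPKM values the authors made beside them. Those deposited RPKM values lie within 2.63% of the count divided by the table's gene length and the library total, and were not used further. The authors also deposited 1 table per patient with a log2 fold change, a log2 CPM, a p-value with its FDR, and an up or down call score for protein-coding genes. In these deposited tables the call equals an FDR under 0.05 for 100% of the genes, without a fold limit; the dispersion the authors assumed for 1 library against 1 is not given in the sources used here. Some genes share reads: of 15503 genes with at least 100 counts in total, 42 had counts identical to another gene in every library, so a read overlapping more than 1 gene was counted for each. Antisense partners are treated as uncertain because the strand setting is unknown. The start and end in the deposited table equal the GENCODE 29 gene span for only 37.9% of genes, so coordinates here are GENCODE 29 gene spans on GRCh38, and 57313 of the kept gene IDs were found there.

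Before any test, 1261 genes were set aside, among them those of chromosome Y and other genes whose levels can mark a person, which left 59407. Groups and patients came from the labels, which name the tumour type and the patient. The pairing was checked as well: deviations from the group means correlated at 0.70, 0.61 and 0.64 within the 3 pairs, and the biological coefficient of variation was 0.30 with the patient as a block and 0.55 without. The libraries differed from each other by far more than sampling noise (chi-square per degree of freedom from 21.8 to 171.8 over the 15 pairs of libraries), so none was treated as a duplicate.

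The main test was edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) on the deposited counts, with TMM factors, the filterByExpr filter by group (minimum count 10, minimum total 15), robust estimation and the patient as a block, and Benjamini-Hochberg adjustment at 0.05. It tested 16349 genes with 2 residual degrees of freedom. The patient block was chosen because the series describes a pairwise comparison within patients. Standard errors of log2 fold changes were derived from the fold change and the F statistic. Levels per library are CPM scaled by TMM factors (0.935 to 1.095) where they accompany a fitted fold change. For genes named within a pair and for list sums, the TMM factors were computed without the filter on low counts.

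Gene lists were 36 sets fixed before the data were examined, covering tumour cell states, pathways, immune functions, other cell types and tissues, and RNA quality. The 33 with at least 5 tested genes entered camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and the patient block, two-sided, with adjustment over the lists. The skeletal muscle, salivary gland and red blood cell lists had too few tested genes, and only their summed CPM is given; the red blood cell sum was 1.04, 2.66 and 5.72 CPM in the primary tumours and 7.30, 2.10 and 12.1 CPM in the recurrences. Camera with an estimated correlation and fry (which tests whether a list's genes move one way on balance, without comparing them with other genes) were run beside it. None of the 12 calls held with an estimated correlation (adjusted p 0.822 to 0.957) or with fry (0.488 to 0.985). On simulated lists over 16349 genes, a list of truly shifted genes had p = 1.6e-05 with the preset and 0.0715 with the estimated correlation, and 5 and 0 of 200 unchanged lists had an unadjusted p under 0.05. The simulated genes varied independently of each other, so this cannot show how the preset behaves for lists whose genes move together. In the real data the estimated correlation was 0.75 for the interferon response list and 0.58 for the macrophage and dendritic cell list. It was −0.03 for oxidative phosphorylation, −0.01 for keratinocyte differentiation and for replication-dependent histones, and −0.09 for B and plasma cells. Those estimates lie below the preset of 0.01, so a raised correlation is not why these calls were lost.

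Within a pair, the log2 ratio of CPM (prior count 2) compares 1 library with 1 and has no p-value. A list's median ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression. The number of genes at least 2-fold changed the same way in all 3 pairs was set against the product of the pairs' shares. From the authors' deposited tables, genes called in the same direction were counted across pairs, and the fixed lists with at least 5 genes in all 3 tables were tested for enrichment with a one-sided Fisher's exact test (scipy 1.17.1).

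Genes named in the text followed a rule fixed before the data were examined: up to 15 genes per direction past the threshold with the same sign in all 3 pairs, filled to 10 per direction with those of smallest p; up to 4 genes of smallest p per list; and within each pair the 5 highest and 5 lowest log2 ratios among genes of at least 10 CPM in a library of the pair. Clone, predicted and antisense names were left out, and some genes that met the rule are not given. Further members of lists and of counts shared between pairs were picked after their values were seen, among them IFIT1, RSAD2, SPP1, CD14, RNA5-8SN4 and the genes quoted from the deposited tables.

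Depth was 4571549 to 11252865 counts, so 3 counts equal 0.267 to 0.657 CPM; such floors cover counting error only. On counts simulated for 3 pairs with the real means and depths, the test recovered 14% of genes changed 2-fold, 82% at 4-fold, 98% at 8-fold and 96% at 16-fold, with 13 false among 158 calls. The changed genes were drawn only from those above a minimum mean count, and each changed by the same fold in every pair. Recovery of genes with low counts, or with changes that differ between patients, was not simulated. The alternatives tried were DESeq2 1.42.0, limma-voom, other scalings, filters, prior counts and thresholds, the fit without the patient block, each pair left out in turn and, chosen after seeing the data, protein-coding genes only.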

Results

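Bulk RNA sequencing was carried out on tumour tissue from 3 patients with oral squamous cell carcinoma, a cancer of the keratinocytes that line the mouth. Each patient gave a primary tumour and a recurrent tumour, so the 6 libraries form 3 pairs of 1 primary and 1 recurrent tumour. The design asks which genes differ between a recurrence and the primary tumour of the same patient. Total counts were 5148917, 5807427 and 6780866 in primary tumours 1, 2 and 3, and 11252865, 4571549 and 8017867 in the matched recurrences. Protein-coding genes took 74.8% to 83.7% of the counts. Small noncoding RNA took 14.9% in recurrence 1 and between 6.2% and 8.0% in the other libraries. The libraries of one patient resembled each other more than those of different patients. The correlation of log2 CPM (counts scaled by library total and TMM factors) across genes was 0.934 to 0.944 within a patient and 0.812 to 0.863 between patients.

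Across the 3 pairs, 2 multi-copy genes passed the test, and both were lower in the recurrences. They were the immunoglobulin heavy constant gamma pseudogene IGHGP (log2 fold change −6.48 ± 0.53, SE, adjusted p = 0.00126) and RNA5-8SN1, a copy of the 5.8S ribosomal RNA gene (−2.77 ± 0.35, adjusted p = 0.0489). Both were lower in 3 of 3 pairs. RNA5-8SN1 lost its call without pair 1 (adjusted p = 0.743), without pair 3 (0.0760) and with RLE size factors (0.0515), and it was not called by limma-voom or with robust=FALSE. IGHGP stood at 1.97, 188 and 1.91 CPM in the primary tumours and at 0, 2.13 and 0 CPM in the recurrences, where 3 counts would correspond to 0.267 CPM in recurrence 1 and 0.375 CPM in recurrence 3. Reads of both genes can also match near-identical copies, so their values are uncertain. The 5.8S copies did not move together: RNA5-8SN3 had −1.21 ± 0.34 (SE, adjusted p = 0.931), the same sign as RNA5-8SN1, whereas RNA5-8SN4 went from 33.0 to 177 CPM in pair 1, from 79.3 to 119 CPM in pair 2 and from 5.87 to 73.8 CPM in pair 3. RNA5-8SN2 went from 5.18, 12.9 and 4.67 CPM in primary tumours 1, 2 and 3 to 13.8, 16.2 and 832 CPM in the recurrences. A further 5.8S rRNA copy had log2 ratios of 5.74, 1.65 and 6.23 in pairs 1, 2 and 3. The fall of RNA5-8SN1 therefore does not stand for all 5.8S copies. The libraries were made to select mRNA, and how much ribosomal RNA stayed in each was not tested. The fall of RNA5-8SN1 need not be a change in the tumours.

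No gene passed as higher among the 16349 tested (edgeR quasi-likelihood test with the patient as a block). In both directions together, 635 genes had an unadjusted p under 0.05, fewer than the share of 0.05 expected if no gene differed. DESeq2 called 31 genes, of which 5 were higher. The count moved most with pair 2: without it, 212 genes passed, 114 higher and 98 lower, and the 2 genes above were among them. Without the pairing no gene passed (84 had an unadjusted p under 0.05), and with protein-coding genes alone, an alternative chosen after seeing the data, no gene passed either (535 at an unadjusted p under 0.05, lowest adjusted p 0.222). The counts of 84 and 535 also lay below a share of 0.05 of the genes tested.

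The genes named next on the lower side were taken by smallest p among those lower in 3 of 3 pairs, and none passed the threshold in the main test; DESeq2 called all those named in this paragraph. FLG2, a filaggrin family protein of the cornified layer, had a log2 fold change of −2.87 ± 0.42 (SE, adjusted p = 0.174), but in pair 2 it stood at 0.175 and 0 CPM, below the level of 3 counts. The protease inhibitor gene A2ML1 had −1.96 ± 0.36 (adjusted p = 0.330), with 460 ± 283 CPM in primary tumours and 177 ± 212 CPM in recurrences (SD, n = 3 each). The cytosolic phospholipase A2 genes PLA2G4E and PLA2G4D, which lie close together on chromosome 15, had −1.85 ± 0.31 and −2.41 ± 0.46; PLA2G4D was at 0.876 and 0.426 CPM in pair 2. ANKRD35 had −1.62 ± 0.29 and CALB1, which encodes the calcium-binding protein calbindin, −2.76 ± 0.46; CALB1 was close to 0 CPM in both libraries of pair 3. IGHM, the constant region of immunoglobulin M, had −4.29 ± 0.66 (adjusted p = 0.310), from 15.1, 63.7 and 4.30 CPM to 1.92, 0.639 and 0.260 CPM.

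On the higher side, IGFBP5, which encodes an insulin-like growth factor binding protein (chromosome 2, 216672105 to 216695525, GRCh38), had a log2 fold change of 1.74 ± 0.33 (SE, adjusted p = 0.310), with 111 ± 57.0 CPM in primary tumours and 365 ± 210 CPM in recurrences (SD, n = 3 each). The interferon-induced genes IFIT2 and HERC5 had 1.59 ± 0.36 (adjusted p = 0.588) and 1.32 ± 0.33 (adjusted p = 0.734). IFIT2 was at 7.09 ± 2.11 CPM in the primary tumours and at 21.5 ± 6.59 CPM in the recurrences (SD, n = 3 each). The pioneer transcription factor gene FOXA1 had 1.74 ± 0.44, the proteoglycan gene SDC2 1.16 ± 0.30, the bile acid and fatty acid ligase gene SLC27A5 1.37 ± 0.35 and the neuropeptide gene NTS 1.83 ± 0.39. NTS and SLC27A5 were below 1 CPM in both libraries of pair 3, and FOXA1 was at 0.318 CPM in primary tumour 3. KLK6, a kallikrein protease gene, had 1.41 ± 0.34, and KRT4, a keratin of mucosal epithelium, 1.60 ± 0.43. KRT4 was at only 0.897 and 0.700 CPM in primary tumours 1 and 2. MIR6510 had 1.97 ± 0.36, but it lies within KRT15 on the same strand, and KRT15 itself had 1.28 ± 0.41, so the 2 cannot be separated at gene level. None of these genes passed the threshold in the main test, and each was higher in 3 of 3 pairs; DESeq2 called IGFBP5, NTS and MIR6510.

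**Figure D1:**
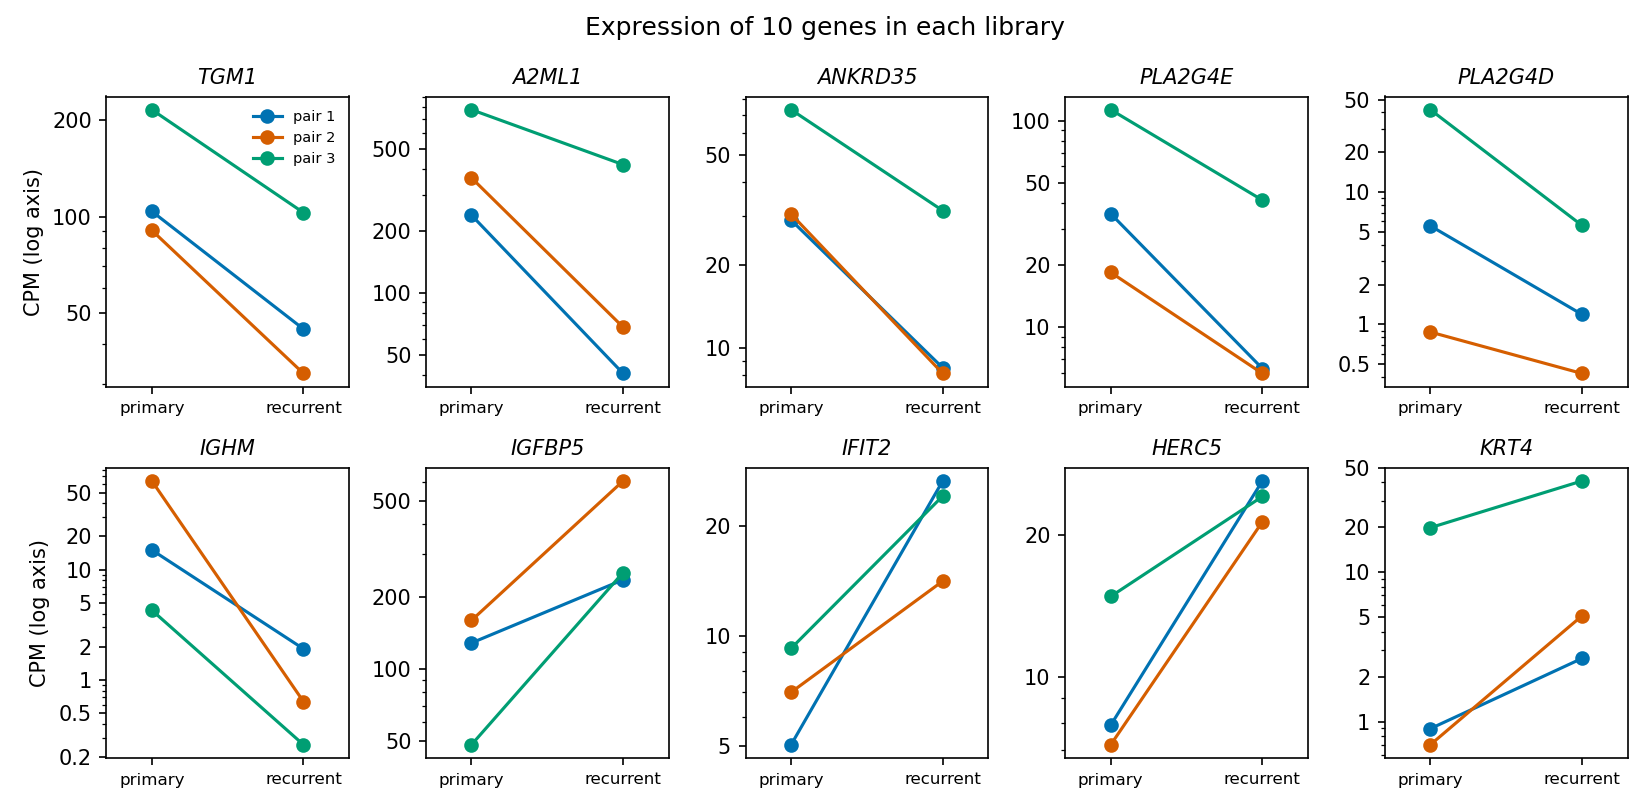
CPM (scaled by TMM factors, log axis) of 10 genes in each library, with a line joining the primary and the recurrent tumour of a pair. The points of TGM1, A2ML1, ANKRD35, PLA2G4E, PLA2G4D and IGHM lie lower in the recurrence of every pair, and those of IGFBP5, IFIT2, HERC5 and KRT4 higher; none of the 10 passed the test over all genes.

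The keratinocyte differentiation list shifted down in the recurrences (camera, adjusted p = 0.00387; adjusted p = 0.822 with an estimated correlation). Of its 34 tested genes, 26 had a fitted fold change below 0 and 10 were lower in all 3 pairs, with list medians of −0.45, −0.13 and −0.55 on the log2 scale in pairs 1, 2 and 3. Adjusted over the list alone, 3 genes passed, against 0 over all genes tested. TGM1, the transglutaminase that cross-links the cornified envelope (chromosome 14, 24249114 to 24264432), was the one that was lower (−1.25 ± 0.25, SE, adjusted p over the list 0.0125), at 137 ± 68.9 CPM in primary tumours and 59.9 ± 37.6 CPM in recurrences (SD, n = 3 each). KLK6 and KRT4 passed in the opposite direction (adjusted p over the list 0.0242 and 0.0356). The desmosomal cadherin gene DSC2 had −0.96 ± 0.32. The list call was lost without pair 3 (adjusted p = 0.149). The basal keratinocyte list did not pass (adjusted p = 0.0754), with medians of −0.26, −0.01 and −0.71, nor did the general epithelial list (adjusted p = 0.974), with medians of 0.08, −0.60 and 0.57.

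The list of nuclear-encoded oxidative phosphorylation genes, which make the mitochondrial respiratory chain and ATP synthase, shifted up by a small amount in every pair (camera, adjusted p = 1.4e-05; adjusted p = 0.822 with an estimated correlation). Its medians were 0.39, 0.32 and 0.29, 28 of 29 genes had a fitted fold change above 0, and 20 were higher in all 3 pairs. COX7C had 0.71 ± 0.28, COX5B 0.62 ± 0.25, NDUFB10 0.61 ± 0.25 and COX6C 0.64 ± 0.28 (SE), and no single member passed. It was the 1 list of the 12 called that kept its call and direction whichever pair was left out. The mitochondrially encoded mRNA list did not pass (adjusted p = 0.0749), with medians of 0.28, −0.16 and 0.51. The small ribosomal protein list shifted up (adjusted p = 0.0195; adjusted p = 0.953 with an estimated correlation), with medians of 0.44, 0.35 and −0.08; RPS27 had 0.58 ± 0.35. The replication-dependent histone list also shifted up (adjusted p = 0.00760; adjusted p = 0.822 with an estimated correlation), with medians of 0.28, 0.31 and 0.14. Both of those calls were lost without pair 1 or without pair 2.

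Most immune lists moved unevenly between pairs. The interferon response list shifted up (camera, adjusted p = 9.0e-07; adjusted p = 0.953 with an estimated correlation), with 27 of 31 genes fitted higher and 9 higher in all 3 pairs. Its medians were 2.00, −0.05 and 0.11, and the call was lost without pair 1 (adjusted p = 0.751). IFIT2 was the 1 gene that passed over the list alone (adjusted p over the list 0.0301); IFIT3 had 1.31 ± 0.45, MX1 0.69 ± 0.25 and OAS2 0.99 ± 0.38 (SE). The macrophage and dendritic cell list, the neutrophil and mast cell list and the list of MHC class I presentation shifted up, each with an adjusted p of 0.0309 (0.957, 0.953 and 0.953 with an estimated correlation). All 3 had medians above 0 in pairs 1 and 3 and below 0 in pair 2, and all 3 calls were lost without pair 1 and, separately, without pair 3. The macrophage and dendritic cell call was also lost with a prior count of 0.5 (camera, adjusted p = 0.0533). The scavenger receptor gene MSR1 had 1.16 ± 0.45, CD68 0.63 ± 0.42, MNDA 0.74 ± 0.38 and B2M 0.69 ± 0.36. The T cell and natural killer cell list shifted down (adjusted p = 0.00579; adjusted p = 0.953 with an estimated correlation), with medians of 0.54, −0.77 and −0.72; IL7R had −0.69 ± 0.32 and PRF1 −0.85 ± 0.55. Without pair 2 its direction turned (adjusted p = 0.981), and without pair 3 its call was lost (adjusted p = 0.333). The B cell and plasma cell list, with 9 tested genes, shifted down (adjusted p = 0.0195; adjusted p = 0.822 with an estimated correlation), with medians of −0.18, −0.51 and −0.57, and lost its call without pair 1 or without pair 2. Its members XBP1, PRDM1 and SDC1 are also expressed by keratinocytes.

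The immediate early and dissociation stress list shifted down (camera, adjusted p = 0.00631; adjusted p = 0.953 with an estimated correlation), with medians of −0.33, −0.80 and 0.24. ZFP36, which encodes an mRNA-destabilising protein, passed over the list alone (−1.04 ± 0.25, SE, adjusted p over the list 0.0343); EGR1 had −0.78 ± 0.28, EGR3 −1.09 ± 0.37 and DUSP1 −0.75 ± 0.27. The hypoxia list also shifted down (adjusted p = 0.00631; adjusted p = 0.953 with an estimated correlation), with medians of 0.07, −0.51 and −0.26. Its members of smallest p were HK2 (−1.09 ± 0.27), which encodes a hexokinase, ANGPTL4 (−1.21 ± 0.36), NDRG1 (−0.90 ± 0.29) and PFKFB4 (−1.04 ± 0.36). Both calls were lost without pair 2 (adjusted p = 0.530 for each), and that of the immediate early list also without pair 1 (adjusted p = 0.0761).

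The other 21 lists with at least 5 tested genes did not pass (camera, adjusted p from 0.0749 to 0.974). They included cell cycle (adjusted p = 0.319), DNA double-strand break repair (0.907), p53 targets (0.912), the partial EMT programme of head and neck cancer (0.907), EMT transcription factors (0.555), stemness (0.781), EGFR family and ligands (0.303), TGF-beta response (0.907) and NRF2 targets (0.555). They also included matrix metalloproteinases (0.974), fibrillar collagen and extracellular matrix (0.514), fibroblast and pericyte (0.0847), endothelial (0.249), adipocyte (0.345), nerve and Schwann cell (0.907), MHC class II presentation (0.540), immune checkpoints (0.663) and inflammatory cytokines (0.352). For the TGF-beta, double-strand break repair, partial EMT and metalloproteinase lists, the median fitted fold change lay slightly above 0 while camera gave a downward direction.

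**Figure D2:**
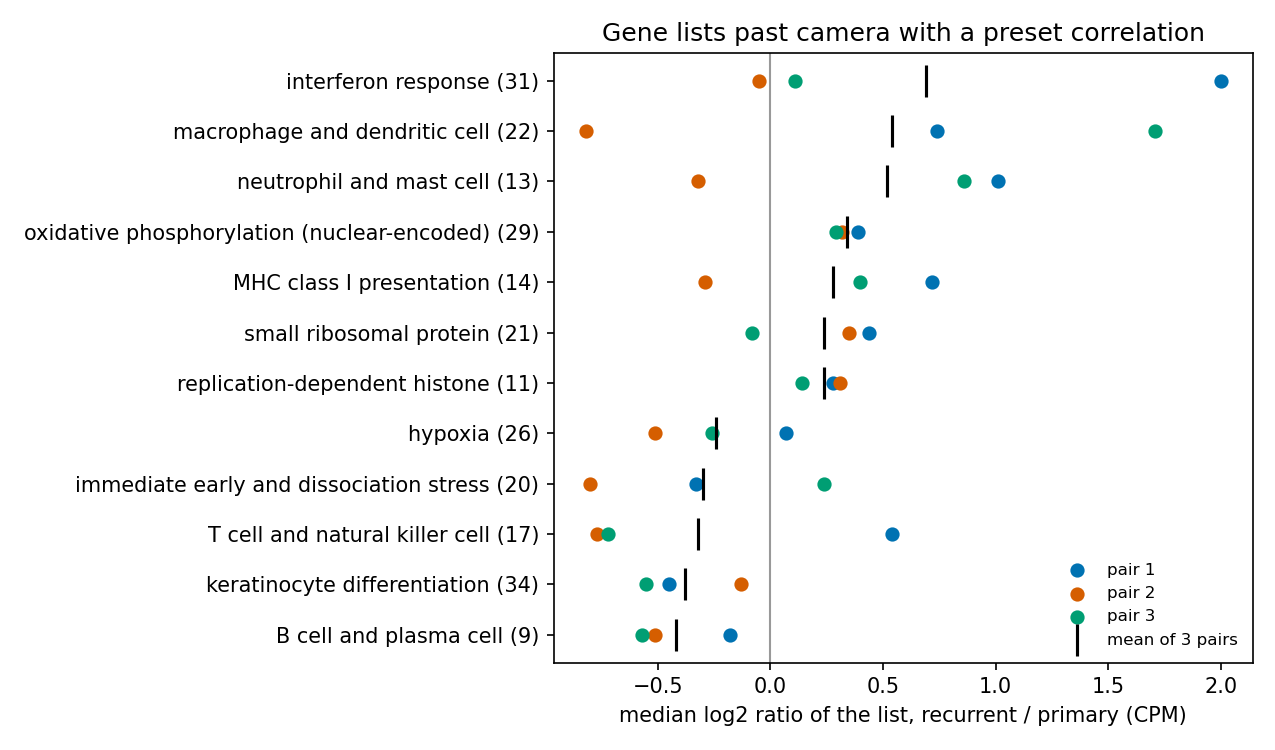
Median log2 ratio (recurrent over primary, CPM) of the 12 lists past camera with a preset correlation, with the number of tested genes in brackets, 1 point per pair and a black bar at the mean of the 3 pairs. The oxidative phosphorylation points lie together at 0.29 to 0.39, whereas those of the interferon list spread from −0.05 to 2.00 and those of the macrophage list from −0.82 to 1.71.

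Within pair 1, interferon genes made the largest list shift. The interferon median of 2.00 lay above those of all 10000 random lists matched on expression, and IFIT1 went from 10.7 to 155 CPM, IFIT3 from 11.1 to 81.8 CPM and RSAD2 from 8.81 to 89.7 CPM. The neutrophil and mast cell median was 1.01, that of MHC class II presentation 0.91 and that of fibrillar collagen −0.51. KRT1, a keratin of suprabasal cells, went from 434 to 2.81 CPM, KIF1A from 16.1 to 0.375 CPM, KRT72 from 10.9 to 0.281 CPM, PLA2G3 from 10.2 to 0.843 CPM and FKBP5, a glucocorticoid-responsive gene, from 178 to 19.7 CPM. Among the highest ratios were GDF15, a stress-induced cytokine gene (1.38 to 44.8 CPM), and IGHA1, the constant region of immunoglobulin A (0.345 to 13.5 CPM). The highest was that of a 5.8S rRNA copy (1.55 to 105 CPM), and the copy RNA5-8SN5 went from 0.691 to 19.7 CPM. These comparisons, and those in the next 2 pairs, set 1 library against 1, have no replicate check and carry no p-value.

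Within pair 2, genes of skeletal muscle and immunoglobulin had the lowest ratios. Summed over the 30 genes of the skeletal muscle list, the level was 2522 CPM in the primary tumour and 84.7 CPM in the recurrence, against 334 and 174 CPM in pair 1 and 102 and 65.4 CPM in pair 3. The myosin genes MYH2 and MYH7 went from 118 to 0.210 CPM and from 54.4 to 0 CPM, and XIRP2 from 98.6 to 0.210 CPM. The immunoglobulin light chain gene IGLC1 went from 433 to 2.52 CPM and the overlapping IGLL5 from 435 to 2.52 CPM, counts that largely come from the same reads. Genes of the salivary gland list summed to 173 CPM in primary 2 and 16.4 CPM in recurrence 2. Whether primary 2 held muscle or gland from beside the tumour is not given in the sources used here, and such tissue was not ruled out as the source of these differences. The medians of MHC class II presentation (−1.13), inflammatory cytokines (−0.88) and macrophages (−0.82) were low, and that of the cell cycle list was 0.55, above all random lists. TRHDE (0.177 to 13.9 CPM), KRT72 (1.06 to 31.3 CPM), SPINK7 (0.531 to 15.1 CPM), MAPK10 (4.25 to 60.7 CPM) and CSPG4 (9.74 to 117 CPM) had the highest ratios.

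Within pair 3, the macrophage list had a median of 1.71 and the inflammatory cytokine list one of 1.39. SPP1, which encodes osteopontin, went from 293 to 3502 CPM, CD14 from 11.3 to 82.3 CPM and the neutrophil chemoattractant gene CXCL1 from 2.71 to 142 CPM. Matrix metalloproteinases (0.67), fibroblasts and pericytes (0.62) and fibrillar collagen (0.50) also had medians above nearly all random lists, and basal keratinocyte genes had a median of −0.71. DSG1, the desmosomal cadherin of upper epithelial layers, went from 1400 to 74.5 CPM, the keratin gene KRT71 from 40.9 to 0.133 CPM and the chemokine gene CCL21 from 10.5 to 0 CPM. Outside the central 95% of the random lists lay 15 of 33 medians in pair 1, 21 in pair 2 and 17 in pair 3. By chance, 5 of the 99 medians would be expected there if the genes of a list moved independently. Lists whose genes move together leave that range more often, so these counts do not measure a change of condition.

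**Figure D3:**
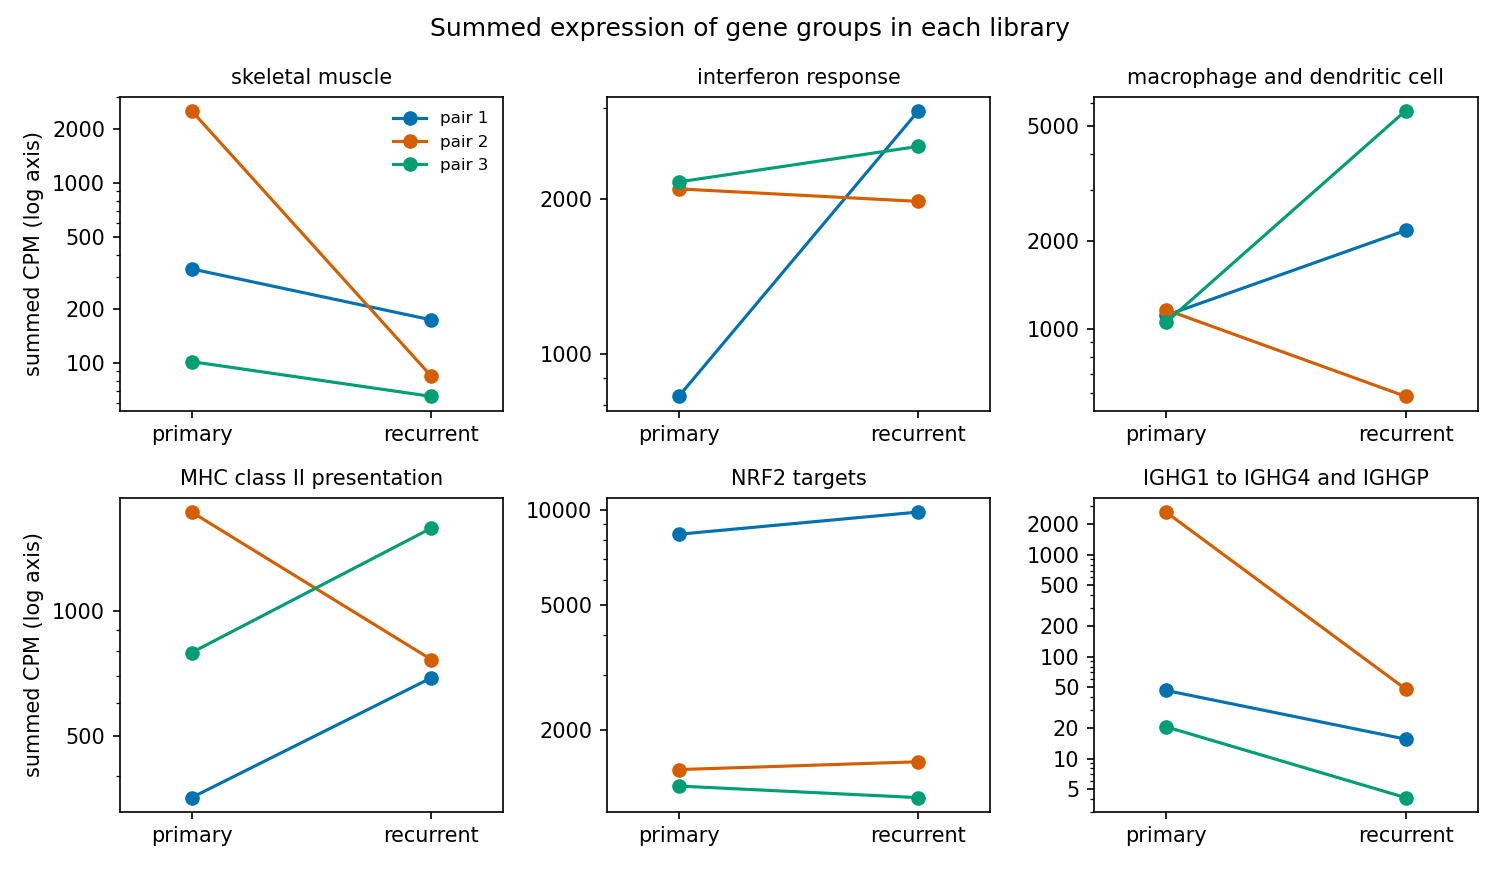
Summed CPM (scaled by TMM factors computed without the filter on low counts, log axis) of 5 gene lists and of the immunoglobulin G constant genes. Each library is shown, with a line joining the 2 tumours of a pair. Skeletal muscle genes stand at 2522 CPM in primary tumour 2, the macrophage list goes from 1050 to 5633 CPM in pair 3 and from 1162 to 584 CPM in pair 2, and NRF2 targets are high in both libraries of pair 1 (8361 and 9832 CPM).

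The 3 pairs had little in common over all genes. The Pearson correlation of their log2 ratios across the 16349 genes was −0.01 between pairs 1 and 2, 0.13 between pairs 1 and 3 and −0.14 between pairs 2 and 3, with a median of −0.01; genes are not independent replicates. At least 2-fold higher in all 3 pairs were 6 genes, where 3.99 would be expected of independent pairs: PABPC4L, AGR2, FMC1, KRT4, MIR6510 and a 5.8S rRNA copy. At least 2-fold lower in all 3 pairs were 31 genes, where 4.96 would be expected. The 31 included 5 immunoglobulin heavy constant genes (IGHM, IGHG1, IGHG3, IGHG4 and IGHGP), TGM1, TGM6, IL36RN, PNPLA1, SLURP2, PLA2G4E, ANKRD35, ELF5 and AZGP1, and the muscle protein genes TTN and TNNT2. TTN, which encodes titin, went from 77.2, 1374 and 58.7 CPM to 16.5, 31.5 and 22.0 CPM, and muscle sampled beside the tumours was not ruled out as its source. In counts simulated for 3 pairs, 19 unchanged genes were 2-fold changed the same way in all pairs, in either direction, to be set beside the 37 here.

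The authors' deposited tables compare the 2 libraries of each pair over protein-coding genes, so their p-values concern those libraries and not the conditions. Leaving out the genes set aside here, the authors' deposited tables called 4000 genes in pair 1 (2074 higher, 1926 lower), 1898 in pair 2 (678 and 1220) and 2654 in pair 3 (1391 and 1263) at an FDR under 0.05. Of the 13843 genes in all 3 of the authors' deposited tables, 6 were called higher in each, where independent lists would share 8.31, and 45 were called lower in each, where independent lists would share 11.38. The 6 higher in the authors' deposited tables were FOXA1, IFIT2, IGFBP5, KLK5, SEMA6A and UQCRH, a respiratory complex III subunit. Among the 45 lower in the authors' deposited tables were TGM1 (log2 fold changes −1.24, −1.48 and −1.08), the stress keratin KRT16 (−1.20, −0.81 and −1.33), the cornified envelope gene SPRR1B (−0.53, −0.92 and −0.86), the epidermal protease inhibitor SPINK5 (−1.33, −1.02 and −0.63), KRT80 (−0.98, −1.17 and −0.63) and the keratinocyte lipid transporter ABCA12 (−0.87, −0.89 and −0.73). The fixed keratinocyte differentiation list held 2 of the 45, where 0.10 would be expected, which did not pass over the 34 lists (one-sided Fisher's exact test, p = 0.00482, adjusted p = 0.164). Genes called in both of 2 pairs of the authors' deposited tables had the same direction in 277 of 554 cases for pairs 1 and 2, in 512 of 822 for pairs 1 and 3, and in 153 of 585 for pairs 2 and 3.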

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

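The alternative with protein-coding genes only was chosen after seeing the data. With 3 pairs, the count of genes past the threshold (2, with 0 higher and 2 lower) was small and moved with most choices, and the causes were not tested except where fewer genes or samples entered by construction. DESeq2 called 31 genes (5 higher, 26 lower) and the fit without a filter on low counts 90 (25 higher, 65 lower); both included the 2 genes. Limma-voom, RLE size factors and robust=FALSE each called 1 gene, IGHGP, and the minimum of 10 CPM in 3 samples called 1, RNA5-8SN1. Library size alone and a threshold of 0.10 called the 2 genes. Without the replicate block, 0 genes passed (0 lower), and the lists rose from 12 to 13 called, with MHC class I presentation lost (adjusted p = 0.188), the other 11 kept and 2 more lists gained. With protein-coding genes only, 0 genes (0 lower) and 12 lists passed. Leaving out each pair in turn gave 2 to 212 genes, 0 to 114 higher and 2 to 98 lower, and 6 to 13 lists. The highest counts of genes came without pair 2 and the lowest count of lists without pair 1.

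With an estimated correlation 0 lists passed, and with fry 0. RLE size factors, library size alone, the minimum of 10 CPM and a prior count of 0.5 gave 10 to 12 lists. Direction turned for 3 lists when a pair was left out: the adjusted p then ranged from 5.2e-09 to 0.981 for T and natural killer cells, from 1.7e-11 to 0.144 for macrophages and from 1.5e-05 to 0.941 for neutrophils and mast cells. The 37 genes changed at least 2-fold in all 3 pairs became 56 with a prior count of 0.5, 23 with a prior count of 5, 16 at 10 CPM or more in 3 samples and 112 without a filter; the lower genes outnumbered the higher in each. The median correlation between pairs stayed between −0.01 and 0.04. The 51 genes shared by the authors' deposited tables became 23 at an FDR under 0.01 and 0 with an absolute log2 fold change over 2. Of the named genes whose fold change in the main test was recomputed, none changed sign; CALB1 gave no value without pair 1 and PLA2G4D none without pair 3. In simulation 14% of genes changed 2-fold were recovered, among genes above a minimum mean count that changed alike in every pair. Depth, number of pairs and variation were not varied separately.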

Other observations

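Tests on cell content and on reads shared between copies were chosen only after the results were seen, as were the fit without pair 2 as a source of gene names and the choice of the genes named from it; the length, GC and split tests were planned before their results were seen. In the fit on pairs 1 and 3 alone, which has fewer residual degrees of freedom than the 2 of the main fit, 212 genes passed. Among those higher there were SPP1 (log2 fold change 2.32), CD14 (2.07), FCGR3A (2.62), CCL2 (2.86), CXCL8 (2.63) and C1QA (1.59), which are expressed by macrophages among other cells, the stress cytokine gene GDF15 (3.98) and the acute-phase gene SERPINA3 (4.34). Genes of epithelial differentiation went both ways. Lower were TGM3 (−2.48), DSG1 (−2.70), KRT10 (−1.72), ALOX12B (−1.97), LOR (−2.75) and FLG2 (−2.86), and higher were S100A7A (3.17), S100A7 (1.70), SERPINB4 (2.31), SERPINB3 (1.72), SPRR4 (1.94) and KLK6 (1.71). In that fit the macrophage and dendritic cell list was higher (camera with the preset correlation, adjusted p = 1.7e-11) and the keratinocyte differentiation list lower (adjusted p = 0.00111). An estimated correlation was not part of that fit, and over all 3 pairs camera with it gave adjusted p = 0.957 and 0.822 for these lists. Pair 2, which was left out, had a macrophage list median of −0.82. In pair 2, SPP1 went from 276 to 74.6 CPM, opposite to pairs 1 and 3. The difference between pair 2 and the others was not tested, since it rests on 1 pair. In the authors' deposited tables, 432 of the 585 genes called in both pairs 2 and 3 had opposite directions.

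Some levels set pair 1 apart from the other libraries. NRF2 targets, which answer oxidative stress, summed to 8361 and 9832 CPM in the primary and recurrent tumour of pair 1 and to between 1224 and 1590 CPM in the other 4 libraries. AKR1C1 was at 1395 and 1232 CPM in pair 1, and between 7.15 and 23.8 CPM elsewhere. KRT14 was at 130 and 141 CPM in pair 1 and from 2293 to 9740 CPM in the other libraries. The keratin gene KRT72 differed in opposite directions, from 10.9 to 0.281 CPM in pair 1 and from 1.06 to 31.3 CPM in pair 2.

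With 3 pairs there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 2 genes and the highest of the other splits 17; 2 of the 10 splits, the real one included, called at least 2. For gene lists the real split called 12 and the highest of the other splits 17; 7 of the 10 called at least 12. Among the 4 splits that part all 3 pairs, genes called were 2 in the real one and 0, 17 and 0 in the others. Lists called were 12 in the real one and 14, 17 and 8 in the others. The number of lists called by camera with the preset correlation therefore does not set the real grouping apart.

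The 45 genes lower in all 3 of the authors' deposited tables had medians of −1.11, −1.34 and −1.04 in the log2 ratios computed here; they were picked for falling, so that size is inflated. Fewer epithelial cells in the recurrences would lower the other epithelial genes as well. The 34 basal and general epithelial genes had medians of −0.04, −0.13 and −0.21, a mean difference of −1.04 ± 0.19 (SD, n = 3 pairs). The gaps of 1.07 and 1.21 in pairs 1 and 2 exceed the SD over those genes (0.67 and 0.88). In pair 3 the gap of 0.83 lies within the SD of 1.29. Genes picked for falling would lie below genes not so picked whatever the cell content, so these gaps cannot decide. Over the 3 pairs the explanation stays open. Removing each pair's trend with transcript length left the mean of the medians at −1.15, and removing the trend with GC content left it at −1.15, against −1.16 before. Both trends were measured on the longest annotated transcript of each gene. The set was picked for falling, so removing a trend over all genes could hardly lift its median. These values therefore cannot decide on either trend. A lower degree of squamous differentiation in the recurrences is a hypothesis these data leave open, along with the place in the tumour that was sampled; neither was tested. KRT4 and KLK6, which point the other way, show that not all genes of the differentiation list moved together.

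The immunoglobulin heavy constant genes IGHM, IGHG1, IGHG3, IGHG4 and IGHGP were lower in all 3 pairs. Reads moving between near-identical gamma genes would leave their sum unchanged, whereas the summed CPM of IGHG1 to IGHG4 and IGHGP went from 46.6, 2626 and 20.5 to 15.5, 48.1 and 4.13, a mean log2 ratio of −3.22 ± 2.24 (SD, n = 3 pairs). Fewer antibody-secreting cells may account for pairs 2 and 3, where the highest log2 ratio among IGHA1, IGKC and JCHAIN was −2.07. Other plasma cell genes, all with low levels, were mixed in pairs 2 and 3. MZB1 (−3.56 and −1.02) and POU2AF1 (−2.65 and −0.47) were lower in both, and DERL3 (0.49 and 0.93) was higher in both. TNFRSF17 was lower in pair 2 (−2.01) and higher in pair 3 (0.54). In pair 2 the primary tumour also had more salivary gland (173 and 16.4 CPM) and skeletal muscle transcripts (2522 and 84.7 CPM), so plasma cells of adjacent tissue in that specimen could bring the same fall, and this stays open. In pair 1 the median log2 ratio of IGHA1, IGKC and JCHAIN was 1.31. However, IGKC was flat there (26.1 and 24.7 CPM) and IGHA1 had 2 counts in the primary tumour. A loss of antibody-secreting cells in pair 1 stays open too. Levels were low outside primary tumour 2, and the difference between pairs was not tested.

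The oxidative phosphorylation list was higher in each pair, with a mean of the medians of 0.34 ± 0.05 (SD, n = 3 pairs). By the longest annotated transcript of each gene, its median length was 1985 bases against 3339 over all tested genes, so RNA quality could shift the list. The expressed transcripts can differ in length from the longest annotated ones. Removing each pair's trend with length left 0.26 ± 0.04, and removing the trend with GC content left 0.35 ± 0.05. Neither trend, as measured on the longest annotated transcripts, is the whole cause. Among the lists fixed for RNA quality, those of small ribosomal proteins and replication-dependent histones also shifted up. The immediate early list shifted down and the mitochondrially encoded mRNA list did not pass, so RNA quality was not ruled out. A higher respiratory gene expression in the recurrences is a hypothesis consistent with these values; a change in cell make-up was not tested for this list, and the call did not hold with an estimated correlation.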
